A study of Danio rerio with 60 samples.

How the data were processed

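The 60 arrays were a zebrafish design of Agilent with 4 arrays of about 44K spots per slide. Per the labels' protocols, total RNA of gonads was amplified and labelled, gonad RNA with Cy5 (red) and the reference pool with Cy3 (green), and no dye swap was used here. The spot intensity values, a mean signal and a median local background for each channel, were deposited as Agilent Feature Extraction 9.5.1.1 wrote them, without normalization, per the file headers of 59 arrays. The file of ovary replicate 121 (14 d, 7 mg) has no header, so its version, slide and scan day are unknown. The log10 ratio of red over green was deposited after background subtraction, spatial detrending and linear and lowess dye normalization by Feature Extraction, per the file headers. The table of values deposited for the series equalled that log10 ratio within 0.005.

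Each array held 44407 spots, among them 1417 controls, for 21495 probes, most spotted in duplicate. Signals were corrected with normexp (offset 50), and log2 ratios of red over green were normalised within each array by loess, with controls and spots of non-uniform signal at weight 0. The spots of a probe were averaged, and for each gene the probe with the highest mean brightness was kept. A gene was tested where red was well above background on at least 4 arrays of the tissue, which left 11460 genes in ovary, 12846 in testis and 13317 in the fit of both. Current symbols were found through RefSeq accessions, symbols and synonyms.

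Differences were tested with limma (lmFit and eBayes; two-sided), with a Benjamini-Hochberg adjusted p under 0.05 within each comparison. Each tissue was fitted alone, with 31 ovary and 29 testis arrays and 6 groups, and comparisons across tissues used a fit of all 60 arrays. Comparisons were severe (1 mg) and moderate (3 mg) hypoxia against 7 mg, 1 against 3 mg, the difference of the 1 mg effect between durations and between tissues, 14 against 4 d at 7 mg, and testis against ovary at 7 mg. Fish were held 4 males and 4 females per tank, per the labels, which do not say which fish shared a tank, so the p-values take each fish as independent. The 4 d fish at 3 mg, 4 testes and 4 ovaries, lie in 1 run of 8 sample numbers. If that run was 1 tank, tank and oxygen cannot be told apart in comparisons with these fish. Comparisons against the same 7 mg arrays share their chance values, and no overlap between them is reported.

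Named genes followed a rule fixed before the data were examined. It took the 10 largest rises and 10 largest falls past the threshold for 1 against 7 mg within a tissue and duration, and 5 and 5 for other comparisons. It added up to 4 members per gene list past the threshold with the smallest p, a set of genes of oxygen sensing, steroid synthesis, germ cells, soma and blood for 1 against 7 mg, and tissue markers for testis against ovary. Where fewer than 5 genes passed, the 5 with a symbol and the smallest p were named with their values. Genes without a symbol were not named, save where stated. Results of 2 genes that the rule selected are not reported here, and counts of genes, named results and outlying samples include them. Members not found by symbol were searched by their name in the files, a step added after the first list results were seen. The genes hmox1a, gsdf and vtg1 of that set were not measured, nor were cyp11c1, zp2.1, gdf9 and bmp15 among the tissue markers.

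The comparisons, tests, alternatives and 31 gene lists, named in the comparison of testis with ovary, were also fixed before the data were examined. Lists were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with the correlation estimated from the data. Of 589 tests 117 passed, and 6 of these passed with an estimated correlation, namely the leukocyte list in testis at 4 d for 1 against 7 mg and for 1 against 3 mg, and the axoneme, zona pellucida, oocyte and endoplasmic reticulum stress lists between the tissues.

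A control chosen after the data were seen set each list member beside 10 genes outside all lists that lay nearest in mean brightness and mean log ratio. The median of these genes equalled at least 0.5 of the list median in 40 of the 117 calls and at most 0.25 in 48. Also chosen after the data were seen were fits on the arrays of a single scan day, slide as a random block, and fits without arrays of unusual brightness (over 1.3 times the median number of spots well above background) or of low correlation (median under 0.75 with arrays of their tissue). The same holds for list tests with scan day or slide in the model, without subtraction of background, with median centring, with Aquantile normalization, with array quality settings and without single arrays.

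The fit was tested on simulated arrays with the spread of the real genes and 200 genes changed by a log2 of 0.5, 1 or 2. For testis at 4 d and 1 mg 44.8%, 77.6% and 98.5% of these were recovered, with 7 false calls of 154. For ovary at 14 d and 3 mg 13.4%, 74.6% and 95.5% were recovered, with 2 false calls of 124. Other splits of the real arrays gave up to 44 and 809 genes there, so this holds for simulated arrays only. Calculations used R 4.3.3 with limma 3.58.1, statmod 1.5.0 and the data.table package at 1.17.8, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.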

Results

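Gonads of adult zebrafish of the AB strain, 7 months old, were profiled after 4 or 14 d in water holding 7, 3 or 1 mg of dissolved oxygen per litre. The labels call 7 mg normoxic, and the study's design text gives a slightly lower figure. RNA of each gonad was hybridised against a common reference pool of gonads and brains of both sexes and livers of females, so every value is a log2 ratio of gonad over reference. The ovary set held 31 arrays: 6 at 1 mg, 4 at 3 mg and 6 at 7 mg after 4 d, and 5 at each level after 14 d. The testis set held 29 arrays: 5 at 1 mg, 4 at 3 mg and 5 at 7 mg after 4 d, and 5 at each level after 14 d.

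The arrays of ovary replicate 121 (14 d, 7 mg) and testis replicates 141 (14 d, 1 mg) and 87 (4 d, 3 mg) were unusually bright. Arrays were scanned on 2 days. In testis at 4 d, 1 of the 5 arrays at 1 mg and 4 of the 5 at 7 mg were scanned on the first day, so scan day and oxygen partly coincide there. A slide held at most 4 arrays, so no values within a slide are given.

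Testis and ovary were compared under normoxia to see how far the 2 gonads differ. Genes of the sperm tail were far higher in testis, and egg coat and oocyte genes far lower. The microtubule gene tuba7l was higher in testis by 10.09 on the log2 scale (SE 0.24; 10 testes and 11 ovaries). The gene tekt1, which encodes a filament protein of the axoneme, was higher by 9.40 (SE 0.18) and sycp3, a component of the synaptonemal complex, by 7.02 (SE 0.15). The Sertoli cell hormone gene amh was higher by 4.44 (SE 0.20) and dmrt1, a regulator of male gonad fate, by 4.23 (SE 0.17). The egg envelope genes zpcx and zp3 stood at -7.96 (SE 0.26) and -5.19 (SE 0.29), and the maternal gene zar1 at -5.82 (SE 0.21). The oocyte transcription factor gene figla stood at -3.77 (SE 0.26) and the ovarian aromatase gene cyp19a1a at -1.96 (SE 0.24). Each of these genes passed limma's test (largest adjusted p 2.05e-10, for cyp19a1a).

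In the same comparison, of 34 measured sperm axoneme genes 31 were higher and 1 lower in testis (median 3.82, camera adjusted p = 1.01e-15, 0.0224 with an estimated correlation), and dnaaf1, needed to assemble the dynein arms, stood at 6.37 (SE 0.14). Of 10 meiosis genes 9 were higher and 1 lower (median 2.56, adjusted p = 0.000654, 0.074 with an estimated correlation). All 9 zona pellucida genes were lower (median -5.75, adjusted p = 3.57e-07, 0.0224 with an estimated correlation), as were 22 of 23 oocyte genes (median -4.39, adjusted p = 2.02e-13, 0.0153 with an estimated correlation). Endoplasmic reticulum stress genes were lower for 15 of 22 members (median -0.96, adjusted p = 0.000654, 0.0238 with an estimated correlation), among them the chaperone gene hsp90b1 at -2.38 (SE 0.12). Proteasome genes were higher for 35 of 41 members (median 1.14, adjusted p = 3.22e-06), ribosomal protein genes for 63 of 67 (median 1.05, adjusted p = 9.01e-08) and respiratory chain genes for 37 of 49 (median 0.71, adjusted p = 0.00214). Those calls were not kept with an estimated correlation, at adjusted p = 0.227, 0.635 and 0.635. Erythrocyte genes were higher for 15 of 19 members (median 1.60, adjusted p = 0.0348, 0.635 with an estimated correlation), led by the carbonic anhydrase gene cahz at 3.37 (SE 0.22).

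The other lists did not pass camera between the tissues, with single members on both sides. Medians were 0.51 for the TCA cycle, 0.46 for glycolysis, 0.10 for fatty acid oxidation, 0.31 for cholesterol synthesis, 1.18 for lipid synthesis and storage, 0.04 for steroid synthesis and 0.21 for gonadal hormone signalling. Among steroid genes the cholesterol transporter gene star was higher in testis at 6.02 (SE 0.24) and hsd3b2 lower at -3.44 (SE 0.22). Gonadal soma genes had a median of 0.57, germ cell genes 1.19, cell cycle genes 0.32, mitochondrial ribosome genes -0.27 and translation factors 0.04. Cytosolic chaperones had 0.31, antioxidant genes 0.25, p53 and apoptosis genes 0.04, hypoxia response genes -0.07 and iron handling genes -0.05. The median was 0.51 for muscle, 0.49 for liver and yolk, 0.40 for leukocyte and inflammation, 0.61 for endothelium and 0.67 for extracellular matrix genes. In all, 9918 of 13317 genes passed limma's test, 5776 higher and 4142 lower in testis, and the median over all genes was 0.13.

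Severe hypoxia for 4 d was compared with normoxia in testis. Genes of leukocytes were higher after 1 mg. The L-plastin gene lcp1 of white blood cells averaged 0.68 ± 0.27 (SD, n = 5) at 1 mg and -1.03 ± 0.25 (n = 5) at 7 mg. This was a rise of 1.70 (3.25-fold; SE 0.28, limma adjusted p = 0.00682). The pleckstrin gene plek rose by 1.64 (SE 0.29) and the phosphatase gene ptpn6 by 1.14 (SE 0.20). The coronin gene coro1a rose by 1.05 (SE 0.17) and the cytokine inhibitor gene socs3a by 1.01 (SE 0.16). The hypoxia-induced genes bhlhe40 and ndrg1a rose by 1.43 (SE 0.25) and 1.22 (SE 0.23). The glutamate transporter gene slc1a1 fell 2.47-fold (log2 SE 0.24) and the water channel gene aqp4 fell by 0.98 (SE 0.20). In each of these genes all 5 testes at 1 mg lay on the same side of the 7 mg mean.

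By limma 37 of 12846 genes passed in testis at 4 d, 28 higher and 9 lower at 1 mg, against 1590 at an unadjusted p under 0.05 where chance gives 642.3. The further named genes that rose were itm2bb, a membrane protein gene, by 2.16 (SE 0.44), and cebpb, a transcription factor gene of myeloid cells and inflammation, by 1.71 (SE 0.37). The granulin gene grna rose by 1.37 (SE 0.30), wasb, which encodes an actin regulator of blood cells, by 1.34 (SE 0.30) and the lipase gene lipf by 1.13 (SE 0.25). The methionyl-tRNA synthetase gene mars1, prrc1 and the zinc finger gene zfr fell by 0.50 (SE 0.11), 0.45 (SE 0.09) and 0.44 (SE 0.08). Genes of oxygen sensing, steroid synthesis and germ cells that were fixed in advance did not pass. The oxygen sensor gene egln3 stood at 1.35 (SE 0.42, adjusted p = 0.167), the lactate dehydrogenase gene ldha at 2.3-fold (log2 SE 0.34), vegfaa at 0.42 (SE 0.22) and igfbp1a at 0.57 (SE 0.48). The androgen synthesis gene cyp17a1 stood at -0.85 (SE 0.37) and star at 0.06 (SE 0.32). The Sertoli cell gene amh stood at 0.20 (SE 0.39), the germ cell gene ddx4 at -0.20 (SE 0.22) and sycp3 at -0.28 (SE 0.19).

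As a list, leukocyte and inflammation genes rose in testis at 4 d: 41 of 49 measured members were higher at 1 mg and the median was 0.53 (camera adjusted p = 4.06e-16, 0.03 with an estimated correlation). Of its members 5 passed over all genes and 25 when adjusted over the list alone. Hypoxia response genes had a median of 0.48 with 19 of 23 members higher, 2 past the threshold over all genes and 9 adjusted over the list alone (camera adjusted p = 9.63e-08, 0.118 with an estimated correlation). Glycolysis genes had a median of 0.30, 18 of 23 higher and 8 past the threshold adjusted over the list alone (camera adjusted p = 7.23e-06, 0.0768 with an estimated correlation). Genes outside all lists that matched the members in brightness and log ratio stood at -0.02, -0.02 and 0.01 in place of these 3 medians. Erythrocyte genes, the markers of blood, had a median of 0.31 and did not pass camera, and the globin gene hbba1 stood at 2.13 (SE 0.87, adjusted p = 0.303).

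Further lists passed camera in the same testes, for 4 of the 5 with matched genes that moved with them. Ovary-typical lists were higher at 1 mg, with a median of 0.88 for zona pellucida genes (adjusted p = 0.000443; 0.338 with an estimated correlation) and 0.41 for oocyte genes (adjusted p = 0.0035; 0.591). Matched genes stood at 0.68 and 0.45, and the oocyte median was 0.23 without 1 mg replicate 93. Sperm axoneme genes had a median of 0.23 (adjusted p = 0.000243; 0.76 with an estimated correlation; matched genes 0.24), and 0.11 without 7 mg replicate 54 (adjusted p = 0.0825). Liver and yolk genes had a median of 0.49 (adjusted p = 0.000585; 0.76 with an estimated correlation; matched genes 0.37). Ribosomal protein genes had a median of 0.25 (adjusted p = 5.07e-11; 0.333 with an estimated correlation; matched genes 0.09), which turned to -0.02 with the red channel alone.

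With scan day in the model 24 genes passed in testis at 4 d, of which 21 were among the 37. In that fit lcp1 stood at 1.52 (adjusted p = 0.0324), plek at 1.75, bhlhe40 at 1.47, slc1a1 at -1.36 and ndrg1a at 0.96 (SE 0.21, adjusted p = 0.0518). Within the first scan day, with 1 testis at 1 mg against 4, lcp1 stood at 2.15 and ndrg1a at 0.50, and within the second, with 4 testes against 1, at 1.62 and 1.09. The leukocyte list kept medians of 0.48 with scan day in the model, 0.43 and 0.55 within the days, the hypoxia list 0.42, 0.13 (past the threshold no longer) and 0.53, and the glycolysis list 0.21, 0.18 and 0.23. All 8 lists passed with scan day in the model, 3 within the first day, where the oocyte median turned to -0.05, 7 within the second and 4 with slide in the model. With slide the leukocyte list kept a median of 0.39 and no gene passed, in a fit with 12 residual degrees of freedom in place of 23. Its values were 1.34 for lcp1 (SE 0.38), 1.75 for plek (SE 0.38), 1.02 for coro1a (SE 0.25) and -1.47 for slc1a1 (SE 0.24), so their lost calls are no sign of a slide effect, while itm2bb and ndrg1a were smaller at 1.36 (SE 0.50) and 0.82 (SE 0.28). The count rested on single fish: it was 17, 56 and 82 without 1 mg replicates 93, 94 and 67, and 23, 21, 24 and 20 without 7 mg replicates 51, 74, 77 and 79.

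**Figure D1:**
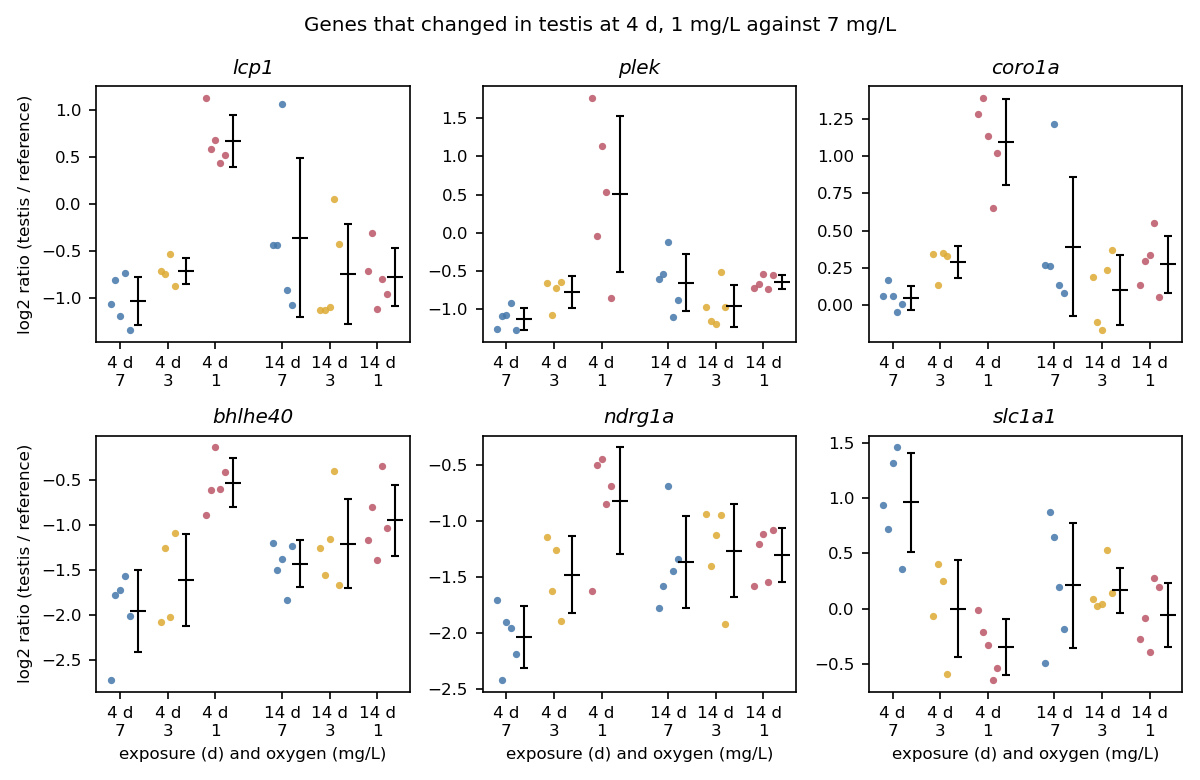
Log2 ratio of testis over reference for lcp1, plek, coro1a, bhlhe40, ndrg1a and slc1a1 in each testis array (points), by oxygen level and duration, with the mean and SD of each of the 6 groups.

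**Figure D2:**
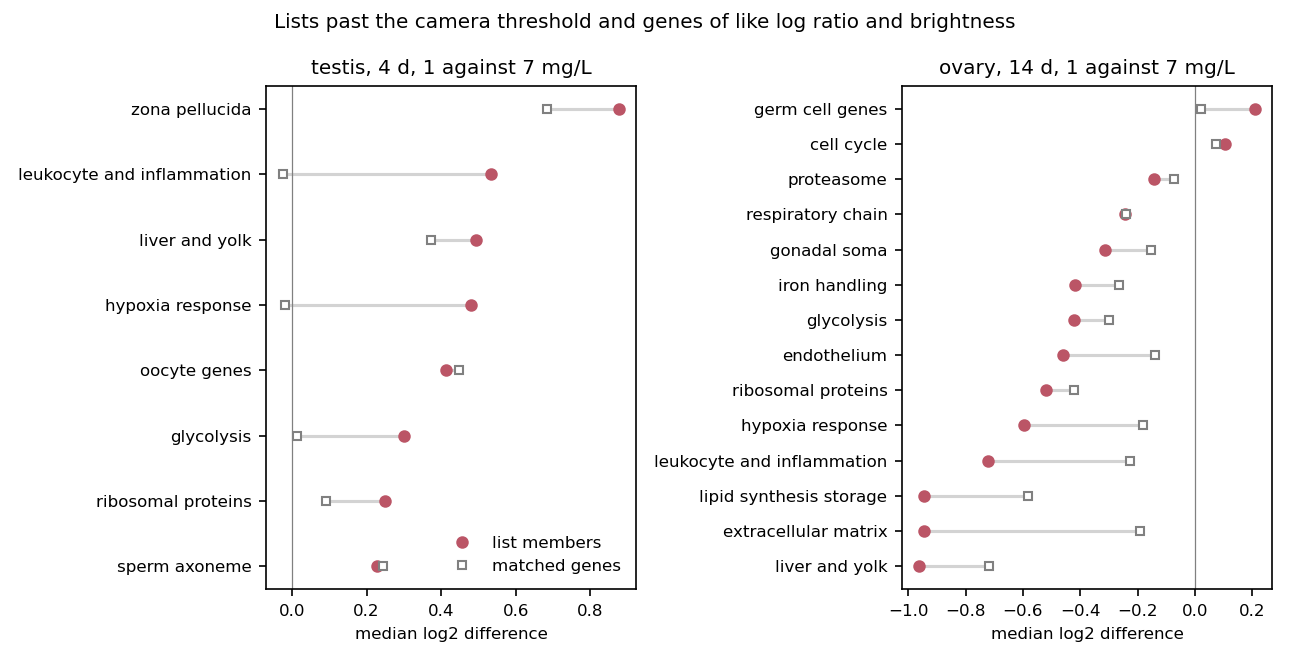
Median log2 difference between 1 and 7 mg of each list past the camera threshold (filled points) beside the median of genes matched on brightness and log ratio (open squares), in testis at 4 d and ovary at 14 d.

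Moderate hypoxia for 4 d was compared with normoxia in testis in the same way. No gene passed limma's test, against 953 at an unadjusted p under 0.05. The smallest adjusted p, 0.156, was that of a gene without a symbol. Nearest of those with one (adjusted p from 0.478) were pdlim5a at -1.50 (SE 0.36), olfml3b at -1.04 (SE 0.26) and dcaf12 at -0.85 (SE 0.21). Next were the ammonium channel gene rh50 at 0.62 (SE 0.16) and the spermine oxidase gene smox at -0.51 (SE 0.13). Zona pellucida genes had a median of 0.85 (camera adjusted p = 4.4e-06) and oocyte genes 0.19, with matched genes at 0.64 and 0.33. Endothelium genes had a median of -0.36, glycolysis genes 0.16, ribosomal protein genes 0.20, respiratory chain genes 0.06, mitochondrial ribosome genes 0.04 and liver and yolk genes 0.25. With an estimated correlation none of these 8 lists passed, at adjusted p from 0.507 to 0.944. Centring of arrays on their median turned glycolysis, ribosomal, respiratory and mitochondrial ribosome genes to -0.03, -0.13, -0.21 and -0.12. The ribosomal median was -0.01 with the red channel alone. All 8 lists passed with scan day in the model and 4 with slide. Within the first day, where the bright replicate 87 was the sole testis at 3 mg against 4, 2 passed and the mitochondrial ribosome, respiratory and ribosomal medians turned to -0.14, -0.02 and -0.01. Within the second (3 against 1) 3 passed.

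Without 3 mg replicate 81 the endothelium and respiratory medians were -0.35 and 0.03 (each at adjusted p = 0.0617), and the ribosomal median was 0.11. Without replicate 87 the oocyte and the liver and yolk medians were 0.23 and 0.13 (adjusted p = 0.0898 and 0.447), and the latter was 0.11 without 7 mg replicate 74 (adjusted p = 0.102). The mitochondrial ribosome call was lost without replicates 81, 82, 51 or 74. Without 1 fish the medians ran from 0.02 to 0.12 for mitochondrial ribosome, 0.03 to 0.09 for respiratory, 0.20 to 0.34 for oocyte and 0.11 to 0.38 for liver and yolk genes.

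Severe was then compared with moderate hypoxia in testis at 4 d. Leukocyte and inflammation genes were higher at 1 mg than at 3 mg, with 44 of 49 members higher and a median of 0.55 (camera adjusted p = 1.95e-15, 0.0367 with an estimated correlation). By limma 4 of 12846 genes passed, all higher at 1 mg, against 1364 at an unadjusted p under 0.05. The actin nucleation gene arpc1b rose by 1.09 (SE 0.20), socs3a by 0.91 (SE 0.17) and the rhomboid family gene rhbdf1a by 0.67 (SE 0.12), each at adjusted p = 0.0385. The remaining gene had no symbol. With scan day in the model the 3 named genes stood at 1.09, 0.91 and 0.67 (each at adjusted p = 0.0419), and within the second day, with 4 testes against 3, at 1.00, 1.11 and 0.54. The first day held 1 testis of each level and is not given. With runs of sample numbers as a random block 1 gene passed, and arpc1b stood at 1.09 (SE 0.21, adjusted p = 0.0883). The lysosomal protease gene lgmn stood at 1.11 (SE 0.22, adjusted p = 0.064) and mafbb, a transcription factor gene of the macrophage lineage, at 1.26 (SE 0.26, adjusted p = 0.0807). Of the leukocyte list 1 member passed over all genes and 21 adjusted over the list alone, and matched genes stood at 0.01.

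Hypoxia response genes had a median of 0.44 between 1 and 3 mg with matched genes at 0.02, endothelium genes 0.48 with matched genes at 0.09, and erythrocyte genes 0.56 with matched genes at 0.10. Their adjusted p was 3.29e-06, 8.1e-05 and 0.00291 by camera and 0.214, 0.214 and 0.513 with an estimated correlation. Sperm axoneme, germ cell and mitochondrial ribosome genes had medians of 0.25, -0.22 and -0.15 and lost their call with an estimated correlation, at adjusted p = 0.658, 0.51 and 0.487. The leukocyte median was 0.55 with scan day in the model and 0.43 within the second day, and all 7 lists passed with scan day in the model, 5 within the second day and 6 with slide. Without 3 mg replicate 83 the erythrocyte median was 0.57 (adjusted p = 0.0519) and that of germ cell genes -0.34. The germ cell call was lost without 1 mg replicates 67 or 93 and 3 mg replicates 81 or 82, with medians from -0.26 to -0.12. The mitochondrial ribosome median was -0.08 and -0.07 without replicates 81 and 82. The gene count was 21 and 15 without 1 mg replicates 67 and 94, 2 without replicate 68, 1 without 1 mg replicates 91 and 93, and 1 without 3 mg replicates 82 and 83.

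After 14 d of severe hypoxia no gene passed limma's test in testis, against 1175 at an unadjusted p under 0.05. Hypoxia response genes had a median of 0.18 with 19 of 23 higher at 1 mg, respiratory chain genes -0.15 with 9 of 49 higher and erythrocyte genes -0.32 with 2 of 19 higher. Their camera adjusted p was 0.000703, 0.000436 and 0.0036, and 0.716 for each with an estimated correlation. Nearest to the threshold of genes with a symbol were anks6 at -0.81 (SE 0.18) and stxbp2, a gene of secretory vesicle fusion, at -0.43 (SE 0.10). Next were snapc3 at 0.35 (SE 0.08), the elastic fibre gene efemp2b at 0.35 (SE 0.09) and selenon at 0.40 (SE 0.10), each at adjusted p = 0.405. Of the genes fixed in advance egln3 stood at 0.90 (SE 0.42), ldha at 0.27 (SE 0.34), cyp17a1 at 1.13 (SE 0.37) and hbba1 at -1.26 (SE 0.87), and none passed. Without 1 mg replicate 138 the hypoxia median was 0.10 (adjusted p = 0.127), without replicate 114 it was 0.30, and without replicate 141 the respiratory median was -0.10. Without 7 mg replicates 122 and 126 the erythrocyte median was -0.31 and -0.38 (adjusted p = 0.0631 and 0.068). All 3 lists passed with scan day or slide in the model, but within the first and the second scan day the hypoxia median was 0.51 and -0.13, the respiratory median -0.26 and -0.02 and the erythrocyte median -0.31 and -0.96.

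Moderate hypoxia for 14 d gave no gene past limma's threshold in testis against normoxia, with 597 at an unadjusted p under 0.05, nor between severe and moderate hypoxia, with 464. The smallest adjusted p against normoxia, 0.73, was that of a gene without a symbol. Nearest of those with one were dhrs9, a retinol dehydrogenase gene, at -1.23 (SE 0.30), anks6 at -0.72 (SE 0.18), gadd45ga at 0.86 (SE 0.24) and nedd1 at -0.50 (SE 0.14). Also near it was the acid sensing channel gene asic4b, which was well above background in no testis at 7 mg and at least 1.84-fold higher at 3 mg. Between severe and moderate hypoxia they were the chromatin insulator gene ctcf at 1.43 (SE 0.33), ppp2r5d at 0.69 (SE 0.17), sort1a at -0.81 (SE 0.22), ndufa4b at 0.90 (SE 0.25) and asic4b, whose fold is not given as it was well above background in 1 of the 5 testes at 1 mg. Against normoxia the lists past the camera threshold were gonadal soma at 0.21, extracellular matrix 0.20, endothelium 0.19, cytosolic chaperones 0.08, ribosomal proteins 0.06, cell cycle -0.10 and liver and yolk -0.37. With an estimated correlation their adjusted p ran from 0.781 to 0.811. Between severe and moderate hypoxia they were extracellular matrix at -0.24, glycolysis 0.12, hypoxia response 0.11, cell cycle 0.09 and respiratory chain -0.10, each at adjusted p = 0.767 with an estimated correlation. Centring of arrays on their median or the red channel alone turned cell cycle medians in both comparisons, ribosomal ones against normoxia, and glycolysis and hypoxia response ones between the levels. With scan day in the model 2 of the 7 and 5 of the 5 lists passed, and with slide 0 and 1. Within the first day 2 and 3 passed and 4 and 1 medians turned, and within the second 1 and 2 passed and 2 and 2 turned, with liver and yolk genes against normoxia at 0.60 (adjusted p = 0.00795).

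Most of these calls in testis at 14 d and 3 mg rested on single fish. Without 3 mg replicate 134 the matrix, endothelium, gonadal soma and cell cycle medians against normoxia were -0.08, 0.05, 0.08 and -0.03, and that of ribosomal genes 0.0018 (adjusted p from 0.292 to 0.749). Liver and yolk genes lost their call in 6 of 10 such fits, with a median of 0.07 without 7 mg replicate 122 (adjusted p = 0.808), -0.06 without replicate 127 (adjusted p = 0.927) and -0.76 without replicate 103. Endothelium genes lost it in 4 of the 10, matrix, gonadal soma and cell cycle genes in 3 each, and cytosolic chaperones without 3 mg replicate 112 (median 0.05, adjusted p = 0.0657). Between the levels glycolysis and hypoxia response genes lost their call in 5 of 10 fits each, cell cycle and respiratory chain genes in 3 each, and matrix genes without replicate 134 (median -0.07, adjusted p = 0.599). There the hypoxia median ran from 0.02 to 0.27 without 1 mg replicate 138 and 3 mg replicate 134, the cell cycle median from 0.0066 to 0.15 without 3 mg replicates 134 and 135, and the respiratory median was -0.04 without 1 mg replicate 141.

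In ovary 4 d of hypoxia gave no gene past limma's threshold at either level. The unadjusted p was under 0.05 for 475 genes at 1 mg against 7 mg, 331 at 3 mg against 7 mg and 256 at 1 mg against 3 mg, where chance gives 573 of 11460. Nearest of genes with a symbol at 1 mg were the DNA repair gene xpa at 1.00 (SE 0.24) and xbp1, a regulator of the unfolded protein response, at -0.80 (SE 0.20). Next were hmbsa of haem synthesis at -0.60 (SE 0.15), the parathyroid hormone gene pth1a at 1.09 (SE 0.29) and the receptor kinase gene rtk4 at 0.60 (SE 0.16). At 3 mg they were elovl4b of fatty acid elongation at -1.54 (SE 0.34), xbp1 at -0.78 (SE 0.22), rnf144b at 0.75 (SE 0.21), hmbsa at -0.55 (SE 0.16) and etv5a at 2.15-fold (log2 SE 0.32). Between 1 and 3 mg they were etv5b at -0.61 (SE 0.14), homer3b at 0.75 (SE 0.19) and tmbim1a at 0.48 (SE 0.13). They were followed by tbpl1, a germ cell relative of the TATA-binding protein, at 0.34 (SE 0.10) and the proton pump gene atp6v0cb at 0.62 (SE 0.19). At 1 mg against 7 mg star stood at -0.92 (SE 0.33), ldha at 0.56 (SE 0.42) and egln3 at 0.30 (SE 0.38).

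Liver and yolk genes were the only list past the camera threshold in ovary at 4 d and 1 mg, with a median of -0.76 against 7 mg (adjusted p = 3.29e-07, 0.894 with an estimated correlation; matched genes -0.48). The median was -0.86 against 3 mg (adjusted p = 4.84e-11, 0.997 with an estimated correlation; matched genes -0.35). Against 3 mg the median was -1.59 within the first scan day, with 5 ovaries against 2, and 0.33 within the second, with 1 against 2. It was -0.78 with scan day in the model, and without 3 mg replicate 88 it was -0.15 (adjusted p = 0.619). Against 7 mg it was -0.58, -0.13 and -0.66 in the same order, with 5 ovaries against 2 and 1 against 4 within the days. Leukocyte and inflammation genes had a median of -0.24 at 3 mg against 7 mg (adjusted p = 0.04, 0.868 with an estimated correlation). It was -0.22, -0.13 and -0.05 without 3 mg replicates 84 and 88 and 7 mg replicate 50 (adjusted p = 0.0803, 0.257 and 0.67), and -0.37 without 7 mg replicate 53. The call was lost with scan day in the model.

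Moderate hypoxia for 14 d gave the longest list of genes of any oxygen comparison in ovary. The Notch target gene her6, a transcriptional repressor, fell by 1.98 (SE 0.36, limma adjusted p = 0.0144), from 0.30 ± 0.51 (SD, n = 5) at 7 mg to -1.68 ± 0.28 (n = 5) at 3 mg. The transcription factor genes mafba, tfap2e and gata6 fell by 2.11 (SE 0.52), 2.03 (SE 0.45) and 1.07 (SE 0.27), and aanat1, which encodes the melatonin synthesis enzyme, fell by 1.99 (SE 0.42). Enzyme genes of glycolysis fell, gpib by 1.48 (SE 0.33) and eno2 by 1.14 (SE 0.29), as did the fatty acid elongase genes elovl5 by 1.44 (SE 0.32) and elovl6 by 0.97 (SE 0.25). The cell cycle kinase gene wee1 rose by 0.66 (SE 0.19).

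By limma 360 of 11460 genes passed at 3 mg, 151 higher and 209 lower, against 2777 at an unadjusted p under 0.05. The other named genes that fell were tuba8l3 at -1.77 (SE 0.47), the glutathione transferase genes gstk1 at -1.71 (SE 0.38) and gstt2 at -0.75 (SE 0.21), and the proteasome genes psme1 at -1.55 (SE 0.42), psmd7 at -0.68 (SE 0.16) and psmc2 at -0.31 (SE 0.09). Also lower were ndufa4b at -1.36 (SE 0.30), the brain-type aromatase gene cyp19a1b at -1.28 (SE 0.32), cfap263 at -0.97 (SE 0.26) and cldnd1a at -0.44 (SE 0.12). The serotonin receptor gene htr5ab rose by 1.04 (SE 0.28), being well above background on 1 of the 5 arrays at 7 mg, csrnp1b by 0.95 (SE 0.23), tbc1d22a by 0.86 (SE 0.22) and the tautomerase gene ddt by 0.86 (SE 0.23). Each named gene had all 5 ovaries at 3 mg on 1 side of the 7 mg mean.

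A fit with scan day in the model, which leaves out 7 mg replicate 121 as its scan day is unknown, passed 6 genes, all among the 360, against 245 without that ovary alone. There her6 stood at -2.34 (adjusted p = 0.0176), -2.15 within the first day and -2.16 within the second. The other genes named here did not pass with it (adjusted p from 0.0743 to 0.164). Some stayed near their size with a wider SE, among them tfap2e at -2.27 (SE 0.51), mafba at -1.98 (SE 0.60), gstk1 at -1.66 (SE 0.44) and gata6 at -1.09 (SE 0.30), and others were smaller, such as gpib at -0.90 (SE 0.27). Within the first day (4 ovaries against 1) and the second (1 against 3) tfap2e stood at -1.43 and -2.75, mafba at -1.09 and -2.42, gstk1 at -0.57 and -2.51, gata6 at -0.43 and -1.82, elovl5 at -0.29 and -1.86 and csrnp1b at 0.01 and 1.51, so a part of scan day stays open. With slide in the model, also without replicate 121, 1 gene passed at 11 degrees of freedom in place of 25. There her6 at -1.90 (SE 0.42), gata6 at -1.04 (SE 0.36) and psmd7 at -0.67 (SE 0.21) lost their call with a wider SE, and cyp19a1b was smaller at -0.53 (SE 0.25). None passed with only the 2 groups in the fit, where folds were unchanged at 8 degrees of freedom, or with the red channel alone, where her6 stood at -1.68 (SE 0.35) and elovl6 turned to 0.07 (SE 0.18). None passed without the arrays of unusual brightness or low correlation, which in ovary are replicates 97, 121 and 128, 3 of the 5 at 7 mg. With runs of sample numbers as a random block 8 passed, her6 among them, and mafba stood at -2.12 (SE 0.55, adjusted p = 0.057). The count was 9, 11, 11 and 132 without 3 mg replicates 132, 107, 105 and 136, and 12, 175, 202 and 1452 without 7 mg replicates 128, 101, 97 and 123.

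At 1 mg for 14 d no gene passed limma's test in ovary, against 2186 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0635. Nearest to the threshold were dachb, a transcription cofactor gene, at 1.32 (SE 0.24) and her6 at -1.95 (SE 0.36). They were followed by the hydrolase gene abhd3 at -1.75 (SE 0.34), mafba at -2.49 (SE 0.52) and the calcium binding protein gene icn at -2.46 (SE 0.52). Of the genes fixed in advance igfbp1a stood at -1.36 (SE 0.49), star at -0.91 (SE 0.36), ldha at -0.89 (SE 0.46) and cyp19a1a at -0.38 (SE 0.39), and none passed. The count was 653 without 7 mg replicate 123 and 326 without 1 mg replicate 139.

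Gene groups in ovary at 14 d were compared with the same 5 ovaries at 7 mg for both levels, so a likeness between the levels carries no evidence on oxygen. At 1 mg extracellular matrix genes had a median of -0.95 with 2 of 24 members higher (camera adjusted p = 9.85e-06, 0.441 with an estimated correlation; matched genes -0.19), and 13 lower and 1 higher past the threshold adjusted over the list alone. Leukocyte and inflammation genes had a median of -0.72 (adjusted p = 1.3e-05, 0.441 with an estimated correlation; matched genes -0.23) and ribosomal protein genes -0.52 (adjusted p = 1.69e-15, 0.441; matched genes -0.42). Hypoxia response genes had a median of -0.60, glycolysis -0.42, lipid synthesis and storage -0.94, and liver and yolk -0.96. Endothelium genes had -0.46, iron handling -0.42, gonadal soma -0.31, respiratory chain -0.24 and proteasome -0.14, while germ cell and cell cycle genes stood at 0.21 and 0.10. None of these 14 lists passed with an estimated correlation, at adjusted p from 0.441 to 0.587. When arrays were centred on their median, glycolysis, respiratory chain and proteasome genes turned to 0.01, 0.17 and 0.28. Without the 3 ovaries at 7 mg of unusual brightness or low correlation 1 of the 14 lists kept its call, extracellular matrix at -0.85, and the cell cycle median turned to -0.03. With slide in the model 3 kept it, namely ribosomal protein, respiratory chain and proteasome genes, and the leukocyte median turned to 0.02.

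At 1 mg the matrix and leukocyte medians without 7 mg replicate 97 were -0.60 and -0.24 (adjusted p = 0.00291 and 0.036). In that fit the hypoxia, glycolysis, endothelium, iron handling, liver and yolk and cell cycle medians were -0.33, -0.31, -0.25, -0.27, -0.47 and 0.04 and did not pass (adjusted p = 0.221, 0.308, 0.147, 0.492, 0.179 and 0.15). Without 7 mg replicate 128 the cell cycle, proteasome and respiratory medians were 0.07, -0.10 and -0.13 (adjusted p = 0.105, 0.052 and 0.0103). Without 1 mg replicate 117 the lipid synthesis, glycolysis and iron handling medians were -0.84, -0.41 and -0.36 (adjusted p = 0.086, 0.13 and 0.112), and without replicate 113 the hypoxia median was -0.40 (adjusted p = 0.0505). Without 7 mg replicate 121 glycolysis and iron handling genes also lost their call (-0.47 and -0.44), and iron handling genes without replicate 101 (-0.36).

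At 3 mg extracellular matrix genes had a median of -0.88 (camera adjusted p = 0.00467, 0.538 with an estimated correlation; matched genes -0.20) and leukocyte and inflammation genes -0.60 (adjusted p = 0.00384, 0.538; matched genes -0.23). Ribosomal protein genes had a median of -0.40, glycolysis -0.43, hypoxia response -0.50, gonadal soma -0.36, respiratory chain -0.18, proteasome -0.13 and liver and yolk -1.03. With an estimated correlation none of the 9 passed, at adjusted p from 0.538 to 0.54. Without 7 mg replicates 97, 121 and 128 together none kept its call and the ribosomal median turned to 0.0025, and with slide in the model 2 kept it, gonadal soma and respiratory chain. Centring of arrays on their median turned glycolysis, respiratory chain and proteasome genes to 0.04, 0.23 and 0.38. Without 7 mg replicate 97 the matrix, leukocyte, glycolysis, hypoxia and liver and yolk medians were -0.50, -0.15, -0.27, -0.44 and -0.44 (adjusted p = 0.236, 0.343, 0.0986, 0.295 and 0.172). Without 7 mg replicate 128 the respiratory and proteasome medians were both -0.07 (adjusted p = 0.113 and 0.117). The hypoxia call was lost in 6 of 10 fits without an ovary, and the liver and yolk median was -1.56 without 3 mg replicate 136.

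Scan day could be set apart only in part in ovary at 14 d, since replicate 123 was the sole 7 mg ovary of the first day, against 2 at 1 mg and 4 at 3 mg, and replicate 97 was among 3 of the second, against 3 and 1. At 1 mg the matrix median was -0.46 within the first day, -1.37 within the second and -1.16 with scan day in the model, the leukocyte median -0.13, -1.13 and -0.88, and the ribosomal median -0.08, -0.72 and -0.54. At 3 mg the matrix median was -0.25, -1.36 and -0.89 in the same order. Of the 14 lists at 1 mg 11 passed with scan day in the model, 0 within the first day and 13 within the second, and of the 9 at 3 mg 6, 0 and 4 passed. Within the first day the glycolysis, hypoxia, iron handling, lipid synthesis and liver and yolk medians at 1 mg turned to 0.09, 0.04, 0.14, 0.03 and 0.46. At 3 mg the liver and yolk, respiratory and ribosomal medians turned to 0.46, 0.0076 and 0.13 within it, the last at adjusted p = 0.0335. Between 1 and 3 mg no gene passed limma's test in ovary at 14 d, with 302 at an unadjusted p under 0.05. Nearest of genes with a symbol were csad of taurine synthesis at 0.82 (SE 0.23), cfap263 at 0.94 (SE 0.26), cast at -0.77 (SE 0.22), ptbp1b at -0.84 (SE 0.26) and dhx38 at -0.55 (SE 0.18). Sperm axoneme genes had a median of 0.14 there and ribosomal protein genes -0.17, with adjusted p = 0.755 and 0.958 with an estimated correlation.

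**Figure D3:**
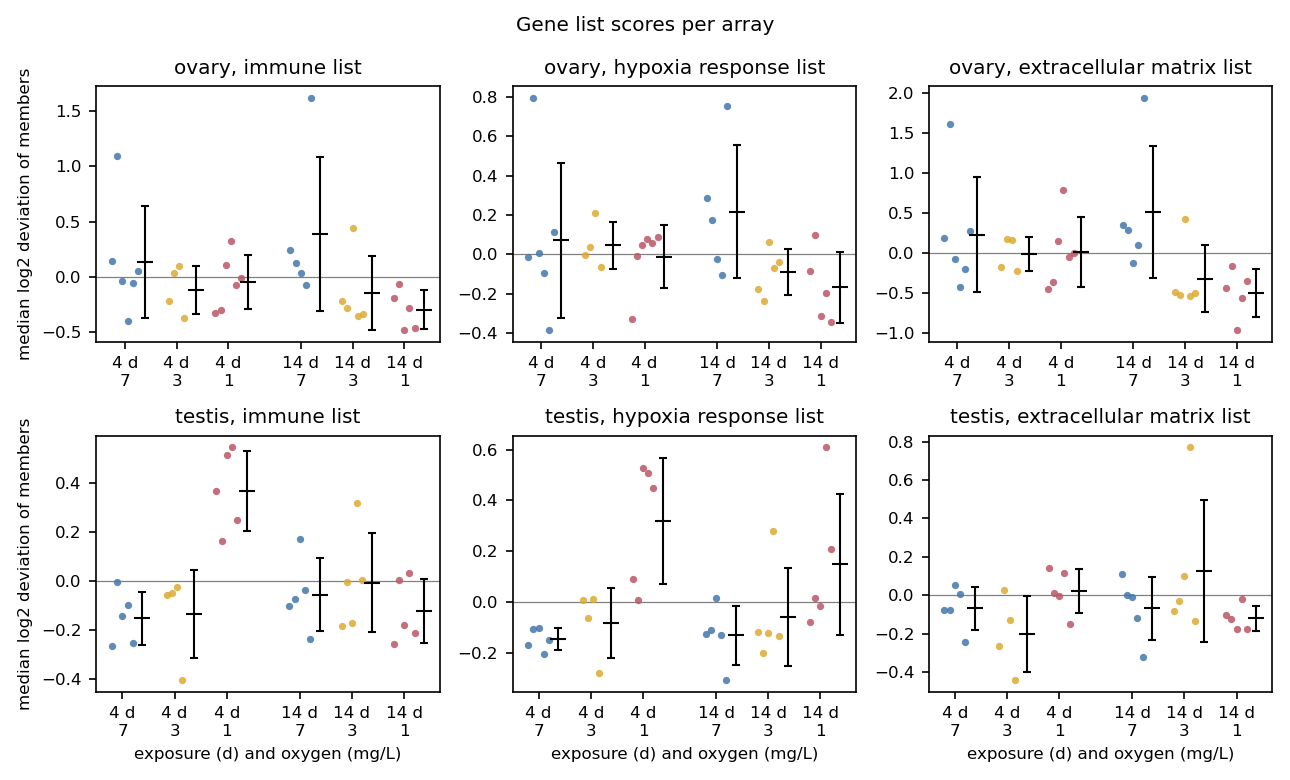
Score of the leukocyte, hypoxia response and extracellular matrix lists in each array (points; median over the list of the log2 deviation from the tissue mean), by tissue, duration and oxygen level, with the mean and SD of each group.

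The effect of severe hypoxia was compared between the durations with an interaction test, which shares no group between its sides. In testis the effect on lcp1, a rise of 1.70 at 4 d, stood at -0.42 at 14 d without passing there (adjusted p = 0.669), and the difference was -2.12 (SE 0.40, limma adjusted p = 0.043). For the small GTPase gene rab1ab the difference was -0.68 (SE 0.13, adjusted p = 0.043). Leukocyte and inflammation genes had a median difference of -0.60 with 5 of 49 positive, 1 past the threshold over all genes and 11 adjusted over the list alone (camera adjusted p = 4.02e-11, 0.143 with an estimated correlation; matched genes -0.03). In all 5 genes passed, against 1240 at an unadjusted p under 0.05. The remaining 3, which carry no symbol, were named in the files CA470137 at 0.79, zgc:64051 at -2.53 and AW076768 at -1.47, chosen for naming after their values were seen. With runs of sample numbers as a random block 1 gene passed and lcp1 stood at -2.11 (SE 0.42, adjusted p = 0.0874). In a fit with scan day lcp1 stood at -2.00 (SE 0.40, adjusted p = 0.0723) and the leukocyte median at -0.64, with -0.35 and -0.69 within the days. The count was 1 without any one of the 4 d replicates 51, 54, 74, 77 and 79 at 7 mg and 68, 91 and 93 at 1 mg. The same held for the 14 d replicates 124 at 7 mg and 114, 119, 138 and 141 at 1 mg. It was 2 without 14 d replicates 122 or 126, and 3 without 4 d replicates 67 or 94 or 14 d replicate 127.

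In ovary no gene passed the interaction test, against 1142 at an unadjusted p under 0.05. Nearest of genes with a symbol were her6 at -2.18 (SE 0.49), the homeobox gene vsx1 at -1.93 (SE 0.45), igfbp3 at 0.87 (SE 0.22) and cthl at -1.49 (SE 0.39).

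Normoxic fish of the 2 durations were also compared. In testis 63 of 12846 genes passed limma's test, 47 higher and 16 lower at 14 d, against 1403 at an unadjusted p under 0.05. The thioredoxin family gene txnl1 was higher by 2.50 (SE 0.42, n = 5 and 5), the F-box gene fbxl3b by 1.54 (SE 0.28), and the retromer gene vps35 by 1.54 (SE 0.35). The melanin synthesis gene dct was higher by 1.34 (SE 0.29) and the calcium channel gene cacna1c by 1.34 (SE 0.26). The androgen synthesis gene cyp17a1 fell by 1.70 (SE 0.37, adjusted p = 0.0346), bpnt1 by 1.36 (SE 0.32), the collagen gene col28a2a by 1.19 (SE 0.26), aqp4 by 1.04 (SE 0.20) and trim25 by 1.04 (SE 0.23). Zona pellucida genes had a median of 0.96 with all 9 higher (camera adjusted p = 1.69e-05, 0.728 with an estimated correlation). The median was 1.07 for liver and yolk genes with all 29 higher (adjusted p = 1.18e-08, 0.728) and 0.43 for oocyte genes (adjusted p = 0.000112, 0.728). Matched genes stood at 0.69, 0.47 and 0.44. Respiratory chain and proteasome genes had medians of -0.08 and -0.13, at adjusted p = 0.728 with an estimated correlation.

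Of the 5 testes of each duration 4 were scanned on the first day, so scan day in the model left cyp17a1 at -1.70 and the zona pellucida median at 0.96, and 139 genes passed with it, among them all 63. Within the first day cyp17a1 stood at -1.46 and the zona pellucida median was 1.06, and the second day held 1 testis of each duration. The count was 0, 8, 10, 111 and 137 without 14 d replicates 122, 124, 103, 126 and 127, and 1, 28, 8, 7 and 20 without 4 d replicates 51, 54, 74, 77 and 79. No gene passed with slide in the model, where txnl1 stood at 2.40 (SE 0.47), fbxl3b at 1.56 (SE 0.33), vps35 at 1.74 (SE 0.38) and cyp17a1 at -1.74 (SE 0.33), each at adjusted p = 0.137. Those lost calls are no sign of a slide effect. With runs of sample numbers as a random block, which would be tanks if fish were numbered by tank, 6 of the 63 passed, and cyp17a1 stood at -1.69 (SE 0.39, adjusted p = 0.0584). None passed with the Feature Extraction ratio, median centring, the red channel alone or only these groups in the fit, where cyp17a1 stood at -1.82 (SE 0.38), -2.01 (SE 0.48), -1.63 (SE 0.36) and -1.70 (SE 0.41). The liver and yolk median was 0.59 and 0.70 without 14 d replicates 122 and 127, and that of proteasome genes -0.08 without 4 d replicate 77 (adjusted p = 0.056).

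In ovary no gene passed between the durations, against 2082 at an unadjusted p under 0.05. Nearest of genes with a symbol were the nucleoside transporter gene slc29a2 at -1.35 (SE 0.25) and chn1 at -1.36 (SE 0.27). They were followed by cptp at 1.86 (SE 0.37), mettl6 at -0.84 (SE 0.18) and drc2, a gene of the axoneme, at 1.33 (SE 0.28), each at adjusted p = 0.0708. Glycolysis, respiratory chain, ribosomal protein and proteasome genes had medians of 0.42, 0.21, 0.20 and 0.14 there, at adjusted p = 0.922 with an estimated correlation. They turned to -0.02, -0.21, -0.24 and -0.32 when arrays were centred on their median. Without 14 d replicates 97, 121 and 128 together the respiratory, proteasome and ribosomal medians turned to -0.0081, -0.01 and -0.20, the last at adjusted p = 0.000157, and the ribosomal median was -0.21 within the first scan day (adjusted p = 0.00624). The ribosomal and proteasome calls were lost in 4 and 7 of 11 fits without an ovary. Without 14 d replicate 97 the glycolysis and ribosomal medians were 0.24 and 0.08 (adjusted p = 0.146 and 0.438), and without replicate 128 the respiratory and proteasome medians were 0.10 and 0.07 (adjusted p = 0.0592 and 0.332). The ribosomal median was 0.33 and 0.36 without 14 d replicate 123 and 4 d replicate 50. The ovary count was 604 without 14 d replicate 123, 127 without 14 d replicate 97 and 77 without 4 d replicate 50.

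The effect of severe hypoxia was compared between gonads as testis minus ovary. At 4 d no gene passed limma's test, against 1259 at an unadjusted p under 0.05. The smallest adjusted p, 0.0603, was that of a gene without a symbol, and nearest of those with one were ndrg1a at 1.48 (SE 0.33), the T cell receptor gene trac at 0.90 (SE 0.21), pfkfb2a of glycolytic control at -1.80 (SE 0.44), prickle1a at -0.52 (SE 0.13) and aqp4 at -1.01 (SE 0.25). At 14 d 3 of 13317 genes passed, against 1685 at an unadjusted p under 0.05. They were efemp2b at 0.80 (SE 0.14, adjusted p = 0.00329), the cytochrome P450 gene cyp3c3 at 1.25 (SE 0.25, adjusted p = 0.035) and a gene without a symbol, named TC271110 in the files, at -1.66, chosen for naming after its value was seen. Next came the calmodulin gene calm1b at 1.48 (SE 0.33), the mitochondrial creatine kinase gene ckmt1 at 2.18 (SE 0.51) and dachb at -1.51 (SE 0.36), at adjusted p = 0.107. In the fit with scan day efemp2b stood at 0.78 (adjusted p = 0.00923) and cyp3c3 at 1.03 (SE 0.22, adjusted p = 0.121). The count at 14 d was 26, 56 and 17 without ovary replicates 128, 123 and 139.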

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

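Of the tests in this part, those of scan day and slide for the immune genes, and of replicate 97 and of unusual arrays for the matrix genes were chosen only after the result was seen, and those of like spots and of the egg coat genes after the patterns but before their own values.

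Leukocyte and inflammation genes were higher in testis after 4 d at 1 mg than at 7 mg, with a median of 0.53, while spots of like log ratio and brightness stood at -0.0245, which argues against an array effect on such spots. Scan day, which partly coincides with oxygen there, may have contributed. In a fit with scan day the median was 0.48 (camera adjusted p = 1.16e-13), which argues against scan day as the whole source. Slide stays open, since with slide in the model the median was 0.39 (camera adjusted p = 7.69e-13; from 1.64e-17 to 8.23e-12 over the alternatives and 0.03 with an estimated correlation), 0.73 of that without it and short of the 0.75 set for excluding it. No single gene passed limma's test with slide, but lcp1 stood at 1.34 against 1.70 and plek at 1.75 against 1.64. These lost calls do not speak for slide. An immune response of the testis to severe hypoxia, or more leukocytes or blood in it, remains a hypothesis among these. Tanks, which the labels do not give, could not be tested.

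Extracellular matrix genes were lower in ovary after 14 d at 3 mg than at 7 mg, with a median of -0.88 (adjusted p = 0.538 with an estimated correlation). Spots of like log ratio and brightness stood at -0.20, which argues against them as the whole source, close to the bound set for that reading. Without 7 mg replicate 97 the median was -0.50 (camera adjusted p = 0.236; from 0.000341 to 0.96 over the alternatives), so a single ovary could have carried the call, and this stays open. Without replicates 97, 121 and 128 together, of unusual brightness or low correlation, it was -0.61 (adjusted p = 0.103), which stays open too, as does an effect of oxygen on the ovary.

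Egg coat genes were higher in testis at 7 mg after 14 d than after 4 d, with a median of 0.96 (adjusted p = 0.728 with an estimated correlation), and their score in the 4 d group was -0.83 ± 0.51 (SD, n = 5) against means from 0.00 to 0.25 in the other testis groups. RNA of ovary in some testis samples may explain this: 120 other genes at least 16-fold higher in ovary had a median of 0.64, and 98.3% of them were higher. Dim spots against a bright reference stay open as well. For 96 genes of as low a log ratio in testis, at a like level in both gonads, the median was 0.80 and 96.9% were higher. Picking genes by low values may itself favour a rise, so this test decides nothing. A change with duration also stays open and was not tested. At 4 d the 120 genes had medians of 0.51 and 0.51 for 1 and 3 mg against that same 7 mg group. This adds no evidence, as the group is shared. Between 1 and 3 mg the median was 0.03.

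Other splits of the same arrays were counted for each comparison, 100 with the real one. At 4 d in testis 37 genes passed for 1 against 7 mg, and 2 of the 100 splits gave as many. The other of these, with 44 genes, followed scan day (0 against 5 arrays of the first day), and with scan day in the model the real groups gave 24 genes. A count of 37 was thus rare among splits, while scan day is not excluded for all of it. For 1 against 3 mg there, with 4 genes, 3 of 100 splits gave as many and the highest other gave 96. For ovary at 14 d and 3 mg, with 360 genes, 3 of 100 did and the highest other gave 809. Such counts were uncommon among splits for both, but 19 comparisons were counted in this way, so chance is not excluded. Splits with such counts point to a structure of the samples other than oxygen. For the testis interaction with 5 genes, the normoxic testes of 14 against 4 d with 63 and testis against ovary with 9918, 1 of 100 splits gave as many, the real one. The highest others gave 3, 4 and 7973, so chance is unlikely for these. For the tissue difference of the 1 mg effect at 14 d, with 3 genes, 19 of 100 splits gave as many and the highest other gave 404, so chance is not excluded and a structure of the samples shows again. Where 0 genes passed, 100 of 100 splits gave as many, and the highest others ran from 3 in ovary at 4 d to 848 in ovary at 14 d for 1 against 7 mg.

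Effects of 1 mg were compared between 14 and 4 d by an interaction test. In ovary the difference had a median of -0.29 for respiratory chain, 0.24 for germ cell, -0.32 for gonadal soma, -0.45 for ribosomal protein, -0.67 for leukocyte and -0.62 for extracellular matrix genes, and none passed with an estimated correlation (adjusted p = 0.769). When arrays were centred on their median, respiratory and ribosomal genes turned to 0.20 and 0.17 there, with the median of all genes at 0.24. Without 7 mg replicate 97 of 14 d the leukocyte and matrix medians were -0.14 and -0.34 (adjusted p = 0.607 and 0.13), and that of germ cell genes was 0.15. Without replicate 128 the germ cell median was 0.17 (adjusted p = 0.0678), and without 4 d replicate 53 the leukocyte median was -0.51 (adjusted p = 0.0543). The matrix median was -0.94 without 4 d replicate 50 and that of gonadal soma -0.49 without 14 d replicate 139. With slide in the model 2 of the 6 lists passed, and the matrix and leukocyte medians turned to 0.22 and 0.11. None of the 6 passed without 14 d replicates 97, 121 and 128 together. In testis it was -0.22 for glycolysis, -0.23 for respiratory chain, -0.86 for zona pellucida, -0.41 for sperm axoneme, -0.19 for ribosomal protein, -0.63 for erythrocyte, -1.004 for liver and yolk and -0.60 for leukocyte genes. With an estimated correlation the leukocyte list stood at adjusted p = 0.143 and the others at 0.672. The zona pellucida call was lost in 11 of 20 fits without a testis (adjusted p up to 0.278, median -0.64, without 14 d replicate 119) and the glycolysis call in 6 (up to 0.159, median -0.11, without 4 d replicate 91). The liver and yolk median was -0.62, -0.52 and -0.59 without 14 d replicates 119, 122 and 127. The genes past the threshold in testis were lcp1 at -2.12, rab1ab at -0.68, CA470137 at 0.79, zgc:64051 at -2.53 and AW076768 at -1.47.

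Effects of 1 mg that differed between testis and ovary at 4 d were medians of 0.54 for hypoxia response, 0.32 for glycolysis, 1.00 for zona pellucida, 0.36 for oocyte and 0.17 for sperm axoneme genes. The medians there were also 0.34 for ribosomal protein, 1.35 for liver and yolk, 0.66 for leukocyte and 0.59 for iron handling genes. None passed with an estimated correlation (adjusted p from 0.361 to 0.721). Without ovary replicate 50 the hypoxia, ribosomal, leukocyte and iron handling medians at 4 d were 0.26, 0.20, 0.37 and 0.42, the last without passing (adjusted p = 0.153). Iron handling genes also lost their call without testis replicate 67 (0.49) and ovary replicate 65 (0.58), and the hypoxia median was 0.35 without the latter. Sperm axoneme genes lost theirs without testis replicates 54 and 93 and ovary replicate 49 (medians 0.07, 0.07 and 0.11). At 14 d they were 0.80 for hypoxia response, 0.57 for glycolysis, -0.28 for germ cell, 0.31 for gonadal soma and -0.11 for cell cycle genes. Further medians were 0.52 for ribosomal protein, 0.47 for leukocyte, 0.41 for endothelium, 0.62 for extracellular matrix and 0.50 for iron handling genes, each at adjusted p = 0.539 with an estimated correlation. Without ovary replicate 97 only hypoxia response (0.49) and ribosomal protein genes kept their call of these 10. The leukocyte, matrix, glycolysis and iron handling medians were 0.20, 0.36, 0.38 and 0.33 in that fit. The gonadal soma, cell cycle and iron handling calls were lost in 12, 9 and 5 of 20 fits without a fish. The germ cell median was -0.20 without ovary replicate 128 (adjusted p = 0.0842) and -0.17 without testis replicate 141. Median centring turned glycolysis and ribosomal protein genes to -0.03 and -0.18 at 14 d, with the median of all genes at -0.21, and the red channel alone turned gonadal soma and endothelium genes to -0.01 and -0.06. The genes past the threshold at 14 d were efemp2b at 0.80, cyp3c3 at 1.25 and TC271110 at -1.66.

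Single samples lay far from the others of their group in 32 of 242 groups of values tested, where chance gives about 1 in 20, or 12.1. The share of red spots well above background was 93.12% in ovary replicate 121 (14 d, 7 mg), 99.18% in testis replicate 141 (14 d, 1 mg) and 95.43% in testis replicate 87 (4 d, 3 mg). Among ovaries of 14 d and 7 mg, cldnd1a was 0.63 in replicate 128, eno2 -5.20 in replicate 123 and cyp3c3 0.83 in replicate 121. The gene mafba was -1.74 in ovary replicate 108 (14 d, 3 mg), cebpb -1.29 and txnl1 0.25 in testis replicate 54 (4 d, 7 mg), and bpnt1 0.84 in testis replicate 124 (14 d, 7 mg).

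Scores of lists, the median log2 deviation of members from the tissue mean, set such samples apart. In ovary replicate 97 (14 d, 7 mg) leukocyte, matrix and oocyte genes scored 1.62, 1.94 and -0.38. In replicate 108 (14 d, 3 mg) leukocyte and matrix genes scored 0.44 and 0.42, and in replicate 50 (4 d, 7 mg) leukocyte, matrix and ribosomal genes 1.09, 1.61 and 0.81. Hypoxia response genes scored -0.33 in ovary replicate 65 (4 d, 1 mg), zona pellucida genes -0.14 in replicate 117 (14 d, 1 mg), 0.0943 in replicate 85 (4 d, 3 mg) and -1.20 in replicate 89 (4 d, 1 mg). Erythrocyte genes scored 0.71 in that last ovary, and oocyte genes 0.12 in replicate 88 (4 d, 3 mg). In testis replicate 134 (14 d, 3 mg) hypoxia response, glycolysis, matrix and liver and yolk genes scored 0.28, 0.12, 0.77 and 1.62. Glycolysis genes scored 0.39 in replicate 138 (14 d, 1 mg) and -0.14 in replicate 83 (4 d, 3 mg), and leukocyte genes -0.41 in replicate 87 (4 d, 3 mg).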

How the results depend on the processing

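A comparison of groups is named here by tissue, duration and levels, and counts are genes past limma's threshold. Of 410 counts recomputed under other settings 298 stayed within 1.5 times the reported one. The 112 that did not are given below, and the cause was not tested except where stated. Single scan days, slide as a random block and fits without unusual arrays were chosen after seeing the data. Pairing was impossible, as sample numbers are unique over the groups.

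Without background subtraction the count was 2 for ovary 14 d 1 against 7 mg, and 4 for ovary 14 d 3 against 7 mg. The count was 2 for testis 4 d 1 against 3 mg, 2 for the testis interaction, 31 for testis 7 mg 14 against 4 d and 1 for the tissue difference at 4 d. With the Feature Extraction log ratio and with the value table, which hold the same values, it was 98 and 100 for ovary 14 d 1 against 7 mg, and 7 and 7 for ovary 14 d 3 against 7 mg. Both gave 2 for testis 4 d 1 against 3 mg and 0 for the testis interaction. Both gave 0 for testis 7 mg 14 against 4 d and 8 for the tissue difference at 14 d. With arrays centred on their median it was 1 for ovary 14 d 1 against 7 mg, 2023 for ovary 14 d 3 against 7 mg, and 19 for ovary 7 mg 14 against 4 d. Centring gave 11 for testis 4 d 1 against 7 mg, 1 for testis 4 d 1 against 3 mg, 1 for the testis interaction, 0 for testis 7 mg 14 against 4 d, and 1 and 1 for the tissue difference at 4 and 14 d. With the red channel alone it was 6 for ovary 14 d 1 against 7 mg, 0 for ovary 14 d 3 against 7 mg, and 1 for ovary 7 mg 14 against 4 d. Red alone gave 4 for testis 4 d 1 against 7 mg, 0 for testis 4 d 1 against 3 mg, 0 for the testis interaction, 0 for testis 7 mg 14 against 4 d and 1 for the tissue difference at 14 d.

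Without the filter on dim probes it was 185 for ovary 14 d 3 against 7 mg and 1 for the testis interaction, and with a stricter one 2 for ovary 14 d 1 against 7 mg. With every probe tested or the mean over probes it was 1 for the testis interaction. With only the groups compared in the fit, which leaves fewer arrays, it was 0 for ovary 14 d 3 against 7 mg and 2 for testis 4 d 3 against 7 mg. Such fits gave 0 for the testis interaction, 0 for testis 7 mg 14 against 4 d and 1 for the tissue difference at 14 d. With all 60 arrays in the fit it was 708 for ovary 14 d 1 against 7 mg, 1133 for ovary 14 d 3 against 7 mg, 2 for the ovary interaction, and 327 for ovary 7 mg 14 against 4 d. This fit gave 7 for testis 4 d 3 against 7 mg, 1 for testis 4 d 1 against 3 mg, 1 for the testis interaction and 208 for testis 7 mg 14 against 4 d. With array weights it was 264 for ovary 14 d 1 against 7 mg, and 681 for ovary 14 d 3 against 7 mg. Weights gave 283, 7 and 433 for testis 4 d 1 against 7, 3 against 7 and 1 against 3 mg, 1 for testis 14 d 1 against 7 mg, 11 for the testis interaction, 419 for testis 7 mg 14 against 4 d, and 90 and 11 for the tissue difference at 4 and 14 d.

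With runs of 8 sample numbers as a random block it was 8 for ovary 14 d 3 against 7 mg. This block gave 1 for testis 4 d 1 against 3 mg, 1 for the testis interaction and 6 for testis 7 mg 14 against 4 d. With scan day in the model it was 1 for ovary 14 d 1 against 7 mg, and 6 for ovary 14 d 3 against 7 mg. Scan day left 24 for testis 4 d 1 against 7 mg, 1 for the testis interaction and 139 for testis 7 mg 14 against 4 d. With slide in the model it was 1 for ovary 14 d 3 against 7 mg, and 937 for ovary 7 mg 14 against 4 d. Slide left 0 and 0 for testis 4 d 1 against 7 and 1 against 3 mg, 0 for the testis interaction, 0 for testis 7 mg 14 against 4 d and 0 for the tissue difference at 14 d. Slide as a random block gave 1 for ovary 14 d 1 against 7 mg. On the first scan day alone it was 0 and 3 for ovary 14 d 3 against 7 and 1 against 3 mg. That day gave 190 and 76 for testis 4 d 3 against 7 and 1 against 3 mg, 2 for testis 14 d 1 against 7 mg, 19 for the testis interaction and 0 for testis 7 mg 14 against 4 d. On the second alone it was 1, 1 and 1 for ovary 4 d 1 against 7, 3 against 7 and 1 against 3 mg, 1 and 1 for ovary 14 d 3 against 7 and 1 against 3 mg, and 8 for ovary 7 mg 14 against 4 d. The second day gave 0 for testis 4 d 1 against 7 mg, 6 for testis 14 d 3 against 7 mg, 0 for the testis interaction, 1 for testis 7 mg 14 against 4 d and 0 for the tissue difference at 14 d. A lone sample in such a fit is assumed to vary like the other groups, and the 76 of the first day and the 1 of testis 7 mg on the second come from 1 array against 1.

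Without the bright arrays it was 90 for testis 4 d 1 against 7 mg, 1 for testis 14 d 1 against 7 mg, 1 for the testis interaction, 144 for testis 7 mg 14 against 4 d and 2 for the tissue difference at 4 d. Without these and the arrays of low correlation it was 0 for ovary 14 d 3 against 7 mg, 90 for testis 4 d 1 against 7 mg, 1 for testis 14 d 1 against 7 mg, 1 for the testis interaction, 144 for testis 7 mg 14 against 4 d, and 9 and 0 for the tissue difference at 4 and 14 d. Calls of lists went from 117 to 6 with an estimated correlation and to 68 on the first scan day alone. Of the 117 calls, 38 were kept in the same direction on the first scan day alone, 65 on the second, 52 with slide in the model and 99 with scan day in it. Kept were 68 without the bright and low correlation arrays, 75 with the red channel alone, 85 with median centring and 86 with array weights.

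Leaving out each array of a comparison in turn gave counts from 0 to 0, 0 to 1 and 0 to 1 in ovary at 4 d and 0 to 653, 9 to 1452 and 0 to 0 in ovary at 14 d. In testis it gave 17 to 82, 0 to 2 and 1 to 21 at 4 d and 0 to 1, 0 to 1 and 0 to 1 at 14 d (1 against 7, 3 against 7 and 1 against 3 mg in each). It gave 0 to 0 and 1 to 6 for the ovary and testis interactions, 0 to 604 and 0 to 137 for ovary and testis 7 mg 14 against 4 d, 0 to 7 and 2 to 56 for the tissue difference at 4 and 14 d, and 9732 to 9998 for testis against ovary.

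Of the genes counted for ovary 14 d 3 against 7 mg, 227 of 2023 with median centring, 332 of 1133 with all 60 arrays and 265 of 681 with array weights were among the 360. The same held for 207 of 372 with slide as a random block and 152 of 245 without the bright arrays. For testis 4 d 1 against 7 mg, 37 of 90 without the bright arrays, 37 of 283 with array weights and 10 of 11 with median centring were among the 37.

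For named genes, a gene that passed in neither setting counts as the same. Directions turned for cldnd1a and psmc2 at ovary 14 d 3 against 7 mg, both 0.17 with median centring, for elovl6 there, 0.0698 with the red channel alone, and for fgg between the tissues, 0.0147 with the mean over probes. Of 321 named results 277 stayed on their side of the threshold with median centring, 261 with the red channel alone, and 269 with the Feature Extraction log ratio. The same held for 287 without background subtraction, 284 with scan day in the model, 260 with slide in the model, 301 with array weights and 288 without the bright and low correlation arrays. Aquantile leaves log ratios as they are, so its 321 unchanged results say nothing of stability.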

Other observations

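Of the tests in this part, those of blood markers and of scan day were chosen only after the result was seen.

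Genes of steroid synthesis in testis at 4 d and 1 mg stood on both sides of 0 against 7 mg, with cyp11a1.1 of cholesterol cleavage at -0.04, hsd3b2 at 0.37, hsd17b3 of testosterone synthesis at -0.44 and the aromatase gene cyp19a1a at 0.51. None passed limma's test.

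Sample descriptions differed from sample titles for ovaries of 14 d, where those of 3 and 1 mg name 7 mg, and groups were taken from the titles. The median correlation of an array's log ratios with other arrays of its tissue ran from 0.648 to 0.936, and with arrays of the other tissue it was at most 0.309.

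A test of blood in the testes for the immune genes at 4 d was set aside. Erythrocyte genes had a median of 0.31 there and did not pass camera (adjusted p = 0.0542), against 0.53 for leukocyte genes. Between 1 and 3 mg erythrocyte genes passed camera at 0.56, against 0.55 for leukocyte genes. No bound was fixed before these values were seen, so blood stays open. Scan day tests for the matrix genes of ovary and egg coat genes of testis were also set aside, with their medians given above.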
